A study of Ovis aries with 6 samples.

How the data were processed

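Per the labels, RNA was taken from the pituitary of 6 sheep, and full-length complementary DNA libraries were made with the Oxford Nanopore kits SQK-PCS109 and SQK-PBK004, which include an amplification step. No molecular identifiers are named. The aligner was minimap2 2.17-r941, per the submitters' processing notes. The quantification tool, the genome build, the annotation and any filter are not given in the sources used here, and no coordinates were used here.

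The deposited data were 2 tables of 26071 rows, estimated counts and TPM per gene. The authors' estimated counts are not normalized, and between 24.0 and 29.8% of the values of a library were not whole, so they were rounded to whole numbers before any test. The authors' TPM values, as deposited, sum to 1000000 in each library. The log2 ratio of TPM to CPM differed between genes, with 5th and 95th percentiles of -4.81 and 2.45 in C1 among genes with at least 50 counts. The TPM were thus not the counts under 1 factor per library, and the lengths behind them are not given in the sources used here. Of each table, 4 rows of annotation text without measurements were left out, which left 26067 features, of which 4610 had no gene name. Of 21457 features with a gene name, 20345 were found under that name in a RefSeq table (assembly ARS-UI_Ramb_v3.0), used for names only. The 13 mitochondrial genes were named through its locus tags. Counts were 0 in every library for 3541 features.

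The labels of the libraries C1 to C6 give no breed, so all 6 were left without a group, no comparison between breeds was fitted, and each library was described by itself. Totals of rounded counts ran from 1981644 in C6 to 2732911 in C2, so that 1 count was worth 0.366 to 0.505 CPM. CPM was the rounded count over the library's total gene count. Levels and shares have 95% Wilson intervals and ratios of 2 libraries exact conditional (Clopper-Pearson) intervals, for counting error only. A count of 0 was set to 3 counts in a ratio, which is then a lower bound.

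Genes with at least 60 counts over the libraries were tested for homogeneity against the library totals by a chi-square test, with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05 and a ratio of at least 2 between the highest and lowest CPM. A gene was detected at 10 counts. For each of 30 gene lists fixed before the data were examined, with at least 3 measured members, the mean log2(CPM + 1) per library was taken, and its range was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list was called wide at percentile 97.5. The lists were hormone genes, markers of somatotrophs, lactotrophs, corticotrophs and melanotrophs, thyrotrophs, gonadotrophs, stem and folliculostellate cells, posterior lobe pituicytes and glia, endothelium, fibroblasts and pericytes, and immune cells. Further lists were hypothalamic neurohormones, red blood cell genes, muscle and bone genes, immediate early genes, GnRH receptor signalling, steroid and nuclear receptors, activin, inhibin and BMP genes, sheep fecundity and seasonality genes, secretory granule, endoplasmic reticulum folding, heat shock, interferon response, cell cycle, cholesterol synthesis, circadian clock, sex chromosome, ribosomal protein, oxidative phosphorylation and mitochondrially encoded genes.

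The genes named were fixed by rule before the data were examined. They were every hormone gene, the 15 genes with the highest median CPM, the 20 genes with a symbol, a mean of at least 10 CPM and the largest ratio among called genes, up to 4 members of each list (2 by median CPM and 2 by ratio), and every fecundity and seasonality gene. Other genes named in the closing section were chosen after their values were seen, as were 10 added gene lists. Some genes that these rules select are not reported here, and such genes were left out of the added lists. The planned correlations between hormone genes across libraries were not run, because the libraries fell into separate sets of fewer than 6.

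The test and the list percentile were tried on simulated Poisson counts, drawn from each gene's share of the summed counts and the library totals. Apart from the raised genes, the simulated libraries did not differ beyond counting error. In the homogeneity test over 13225 genes, 92% of the genes raised 3-fold in 1 library and 100% of those raised 6-fold were called, with 5 unchanged genes called. A list raised by 1 log2 unit in 1 library was at percentile 100 and an unchanged list at 43.2. The real libraries differed more, with a chi-square of 6.32 per gene in the closest pair, C1 and C2. The simulation therefore checks the calculation only, and gives neither the false calls nor the power in these data.

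Alternatives were other count minimums, ratio thresholds and pseudocounts, counts thinned to the smallest library, scaling by edgeR TMM factors or DESeq2 size factors, the authors' TPM, the median in place of the mean, Pearson's r, and leaving out each library in turn. The libraries C4, C5 and C6 alone were an alternative chosen after seeing the data. No test of differential expression was run with edgeR or DESeq2. Software was R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.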

Results

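Full-length complementary DNA from 6 sheep (Ovis aries) was sequenced on Oxford Nanopore devices. The labels give the tissue of every library as pituitary. The study's design describes 3 small-tailed Han sheep, a breed taken as the high-reproduction group, and 3 Wadi sheep, taken as the low-reproduction group. The labels name the libraries C1 to C6 and put none of them in a breed. No comparison between breeds was therefore made, and each library is reported by itself, with no replicates. The libraries C1 to C6 held 2332067, 2732911, 2642721, 2284589, 2419526 and 1981644 gene counts, in that order, the order used for every list of 6 values here. Levels are counts per 1000000 gene counts (CPM). Intervals are 95% intervals for counting error only, because reads of amplified complementary DNA without molecular identifiers are not independent molecules.

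PRL (gene-PRL), which encodes prolactin, reached 120997 CPM in C4, 246764 CPM in C5 and 41508 CPM in C6, against 99.9, 29.6 and 28.0 CPM in C1, C2 and C3. Growth hormone, GH, was at 7.29, 2.93, 4.16, 16344, 34210.4 and 3818 CPM, and the ratio of its highest library (C5) to its lowest (C2) was 11687-fold (95% interval 5931 to 27071). CGA, the alpha subunit shared by the glycoprotein hormones, was at 29.6, 13.5, 17.0, 3687, 14364 and 1478 CPM. The gonadotropin beta subunits had the same highest library, C5, with LHB at 2920.0 CPM (95% Wilson interval 2853 to 2989) and FSHB at 789 CPM (755 to 826). LHB had 5, 1 and 1 counts in C1, C2 and C3, and FSHB had 1, 0 and 0. TSHB, the thyrotropin beta subunit, had 0 counts in C1, C2 and C3, with 95% Wilson upper limits of 1.65, 1.41 and 1.45 CPM. It stood at 7.44, 356 and 18.7 CPM in C4, C5 and C6. POMC, the precursor of corticotropin, was the hormone gene with its highest level in C4, at 394 CPM, followed by 254 CPM in C5 and 112 CPM in C6, with 0, 2 and 2 counts in C1, C2 and C3. Some sheep carry a near-identical second copy of GH, so the count of that gene is uncertain where such reads were split.

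The 7 hormone genes together took 30.0% of the gene counts in C5 (95% Wilson interval 29.9 to 30.0%), 14.2% in C4 (14.2 to 14.3%) and 4.71% in C6 (4.69 to 4.74%). The share was 0.0139% in C1 (0.0125 to 0.0155%), 0.00472% in C2 (0.00397 to 0.00561%) and 0.00503% in C3 (0.00425 to 0.00596%). The median over the 6 libraries was 2.36%, a value that lay between those of C1 and C6 and near neither. It moved to 4.71% with C1, C2 or C3 left out and to 0.0139% with C4, C5 or C6 left out. In the authors' TPM values the shares were 0.00394, 0.00142, 0.00178, 9.23, 21.1 and 2.50%. Of 14 genes of cerebellar granule neurons and Purkinje cells, chosen after their values were seen, 13 exceeded 10 CPM in C1, 13 in C2 and 13 in C3, against 1, 1 and 3 in C4, C5 and C6.

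**Figure D1:**
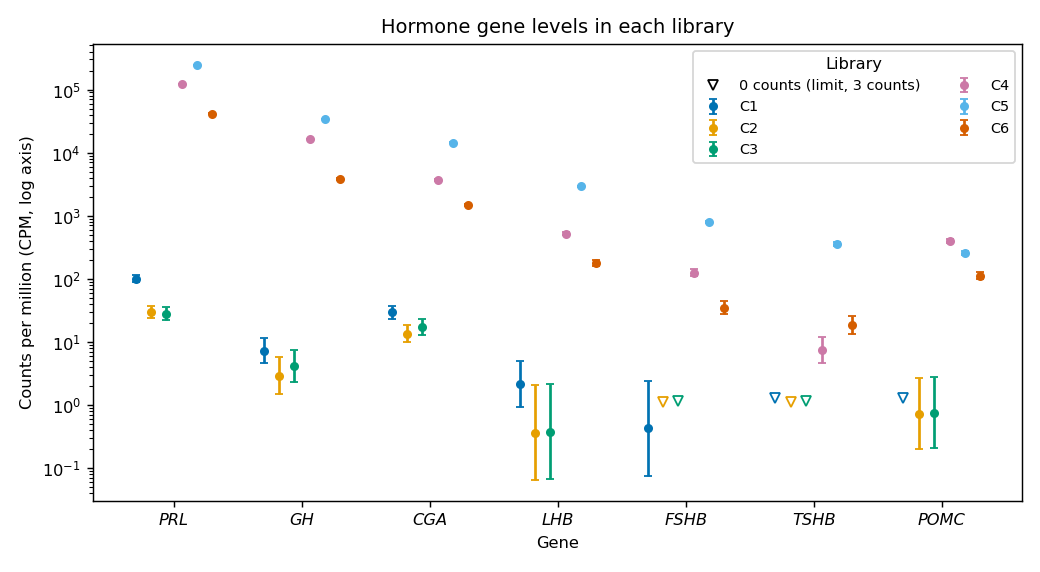
CPM of the 7 hormone genes (log axis) in the libraries C1 to C6, with points for each library and bars for the 95% Wilson interval of counting error. Open triangles mark 0 counts, drawn at the limit that 3 counts would give. PRL lies at 41508 CPM or above in C4, C5 and C6 and at 99.9 CPM or below in C1, C2 and C3.

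Markers of the hormone-producing cell types also differed between libraries. These lists include the hormone genes: FSHB, LHB and CGA for gonadotrophs, GH for somatotrophs, PRL for lactotrophs, TSHB for thyrotrophs and POMC for corticotrophs. Of all genes tested, 80.9% were called as differing, so counts of members that differed are to be read against that share. All 5 measured gonadotroph markers differed between libraries, 4 of them with their highest level in C5, where GNRHR, the receptor for gonadotropin-releasing hormone, reached 71.9 CPM against 15.8 in C4, 6.06 in C6 and 1.72, 1.83 and 0.378 in C1, C2 and C3. All 5 measured lactotroph markers differed. POU1F1, the transcription factor of the lactotroph, somatotroph and thyrotroph lineages, had 0 counts in C1, C2 and C3 and 18.4, 60.3 and 5.05 CPM in C4, C5 and C6, while ANGPT1 was present throughout, at 26.6, 31.1, 41.2, 243, 143 and 87.8 CPM. The 3 measured somatotroph markers differed, among them the retinoid receptor gene RXRG at 33.1 CPM in C5. All 5 measured thyrotroph markers differed, but in different directions. DIO2, the deiodinase that activates thyroid hormone, was highest in C5 at 183 CPM, while TRH, which encodes thyrotropin-releasing hormone, stood at 93.5, 146 and 120.0 CPM in C1, C2 and C3 and at 0 counts in C4, C5 and C6. All 5 measured corticotroph and melanotroph markers differed, again in opposite directions. The neuronal and corticotroph transcription factor NEUROD1 was at 819, 880.4, 581, 1.75, 1.24 and 1.01 CPM, while POMC was highest in C4.

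Each list's mean level per library, as log2(CPM + 1), was set against 10000 random lists matched on expression. The range from the lowest to the highest library was 10.34 for the hormone genes, 7.66 for gonadotroph, 7.61 for somatotroph and 5.54 for lactotroph markers, each at percentile 100 and so among the lists called wide. Thyrotroph markers, with a range of 2.33, were at percentile 96.4, and corticotroph and melanotroph markers, with 0.57, at percentile 7.99. The thyrotroph list was wide under TMM scaling (percentile 97.8), DESeq2 scaling (98.7), in TPM (99.7) and with the median over members (99.8), but was at 65.5 with a pseudocount of 0.1 CPM. With the median over members in place of the mean, somatotroph markers were at percentile 92.2 and lactotroph markers at 94.3, no longer wide. The cell type lists share members with the hormone list, so their ranges are not independent of it. Within C4, C5 and C6 alone, a setting chosen after the values were seen, the hormone, gonadotroph, lactotroph, somatotroph and thyrotroph lists were at percentiles 100, 100, 99.6, 98.6 and 99.3, so these 3 libraries also differed among themselves. C5 was the highest and C6 the lowest of the 3 in each.

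Genes tied to fecundity or seasonality in sheep were mostly near the limit of detection. BMP15, B4GALNT2, KISS1, GNRH1 and NPVF had 0 counts in every library, and FSHR, LHCGR, DIO3 and KISS1R had at most 1 count in any library. MTNR1A, the melatonin receptor gene, had 5 counts in C5 and 0 elsewhere. BMPR1B, the receptor gene of the Booroola fecundity locus, had 12, 8, 12, 2, 5 and 12 counts, GDF9 had at most 6 and INHA at most 16, below the minimum for a test. The 5 measured members were DIO2, ESR1, TAC1, LEPR and EYA3, and 4 of them differed. ESR1, an oestrogen receptor gene, was highest in C5 at 64.9 CPM, then 31.5 CPM in C4, with 4.29, 5.12, 4.92 and 7.06 CPM in C1, C2, C3 and C6. TAC1, the tachykinin precursor, was at 35.5 CPM in C5 and at most 5.25 CPM elsewhere. LEPR, the leptin receptor gene, ranged from 1.10 to 10.9 CPM. EYA3 ranged from 10.6 to 20.2 CPM, with a chi-square test adjusted p of 0.0320 but a ratio of 1.90, under the minimum of 2. The list had a range of 2.38, at percentile 96.4. It was wide under TMM scaling (percentile 98.2), DESeq2 scaling (99.1) and in TPM (99.4). PRLR, another member of this list, was not analysed here.

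Of the genes of GnRH receptor signalling, 29 of 31 measured members differed. Of these, 7, 4 and 10 had their highest level in C1, C2 and C3, and 3, 1 and 4 in C4, C5 and C6. The list mean was highest in C3 under CPM and both scalings but in C4 in TPM. The receptor gene GNRHR itself was at 1.72, 1.83 and 0.378 CPM in C1, C2 and C3. The median of 8 general neuron genes, a list chosen after its values were seen, was 1361, 1407, 1369, 51.9, 56.4 and 70.1 CPM. The phospholipase gene PLCB1 was at 869, 697, 764, 252, 212 and 131 CPM, and the kinase gene CAMK2B was highest in C2 at 58.2 CPM and lowest in C4 at 4.81 CPM. Of the steroid and nuclear receptor genes, 4 of 6 differed, with the glucocorticoid receptor NR3C1 at 171, 129.5, 190.3, 53.0, 33.9 and 92.3 CPM and the thyroid hormone receptor THRA at 106, 129.5, 124, 54.7, 34.3 and 79.7 CPM. Among activin, inhibin and BMP genes, 11 of 16 differed. BMP7 reached 59.5 CPM and FSTL3 22.7 CPM in C6, SMAD5 ranged from 58.3 to 141 CPM, and BMPR1A differed by 1.55-fold (95% interval 1.23 to 1.95), under the minimum of 2 (chi-square adjusted p = 0.00393). The 3 lists were at percentiles 86.6, 14.3 and 33.4. The shares of members that differed in the steroid receptor and activin lists were below the 80.9% of all genes tested.

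Markers of supporting and neighbouring cell types separated the libraries in part along other lines. The stem and folliculostellate and the immune lists, like the hormone genes, had lower means in C1, C2 and C3 than in C4, C5 and C6. All 10 measured fibroblast and pericyte markers differed, 7 with their highest level in C4 and 3 in C6. The collagen genes COL1A2 and COL3A1 reached 538 and 270.1 CPM in C4, and SPARC, a matrix protein gene also expressed by glia, 6452 CPM in C6 against 119 to 668 CPM elsewhere. All 7 measured endothelial markers differed, 4 of them highest in C4, with VWF at 75.3 CPM, PECAM1 at 40.7 CPM and EMCN at 39.8 CPM, while FLT1 was highest in C2 at 109 CPM. Of 10 measured stem and folliculostellate markers, all differed. S100B, which is also a glial gene, was at 3297, 4492, 4113, 103, 99.6 and 9343 CPM and S100A1 was highest in C6 at 146 CPM, while ALDH1A1 (438 CPM) and KRT8 (78.1 CPM) were highest in C5. All 4 measured posterior lobe and glia markers differed, 3 of them highest in C6. The water channel gene AQP4 stood at 188 CPM in C6, against at most 26.5 CPM in any other library, whereas CNTNAP2, a neuronal adhesion gene, was at 1548, 1575, 1448, 155, 111 and 149 CPM.

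All 10 measured immune markers differed. CTSS and CSF1R were highest in C6 (504 and 46.9 CPM), and CD74 was at 147, 159.9 and 149.9 CPM in C4, C5 and C6 against 14.2, 15.7 and 9.84 CPM in C1, C2 and C3. CD3E did not exceed 10.3 CPM. The haemoglobin gene HBB, the measured member of the red blood cell list, was at 12, 16.8, 19.3, 36.8, 0.413 and 45.4 CPM. Of the muscle and bone genes 2 were measured, and both differed, with DES (desmin) at 621 CPM in C4 and 1.65 to 28.0 CPM elsewhere, and ACTA1 between 1.01 and 15.4 CPM. Neither AVP nor OXT reached the minimum, and the sex chromosome genes of the list were not analysed here. The percentiles were 100 for fibroblast and pericyte, 99.98 for posterior lobe and glia, 99.93 for stem and folliculostellate, 99.5 for immune and 99.4 for endothelial markers. The endothelial list was at percentile 96.4 in TPM and 95.6 with a pseudocount of 0.1 CPM. Within C4, C5 and C6 alone, the stem and folliculostellate list was at percentile 87.2 and the immune list at 79.5, no longer wide.

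All 17 measured immediate early genes differed, 13 of them highest in C4, the library with the highest level of most fibroblast and endothelial markers, with the stress-responsive factor ATF3 at 235 CPM against 0.429 to 6.20 CPM elsewhere. IER2 and KLF6 were also highest in C4, at 237 and 249 CPM, and NR4A1 was highest in C5, at 248 CPM. Interferon response genes had the same highest library in 10 of 11 measured members, all of which differed. The antiviral genes MX1, IFI6 and RSAD2 were at 159, 142 and 61.7 CPM in C4, and at 96.7, 47.5 and 14.1 CPM in C5. Both lists were at percentile 100, and within C4, C5 and C6 alone at 100 and 99.9. Of the heat shock genes 7 of 9 differed. HSPB1 and HSPA6 were highest in C4 (711 and 38.5 CPM), while HSP90AA1 and HSPA8 stayed within ratios of 1.86 and 1.55, and the list was at percentile 85.3, and at 99.6 in TPM.

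All 14 measured cholesterol synthesis genes differed, and 12 had their highest level in C6, including SQLE (174 CPM), IDI1 (116 CPM), FDFT1 (68.1 CPM) and SC5D (47.4 CPM). FDFT1, which makes squalene, was at 2.65 to 13.6 CPM in the other 5 libraries. In the same library all 4 measured peripheral myelin and Schwann cell genes and all 6 measured oligodendrocyte genes, lists chosen after their values were seen, were highest by at least 2 times. The cholesterol list was at percentile 99.2, and at 99.95 within C4, C5 and C6 alone. Mitochondrially encoded genes were highest in C6 for 9 of 12 members and lowest in C5 for all 12. ND2 was at 6872, 9384, 8852, 4279, 1489.5 and 14257 CPM and COX3 at 5615, 6691, 5397, 2077, 1343 and 7916 CPM. ND3 was lowest in C5 at 249.6 CPM and highest in C2 at 2408 CPM. The list was at percentile 99.93. Nuclear-encoded oxidative phosphorylation genes stayed closer together, with 26 of 65 past the test and percentile 6.38, although the percentile was 97.9 in TPM. In this list ATP5F1B was at 2087, 2318, 2023, 867, 780.3 and 875 CPM, NDUFA4 ranged from 122 to 814 CPM, NDUFAF8 from 2.56 to 18.7 CPM, and ATP5F1A had a ratio of 1.62.

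Of 19 measured endoplasmic reticulum folding genes 17 differed, 14 of these with their highest level in C5, the library with the highest hormone share. HSPA5, the main chaperone of that compartment, was at 479, 596, 558, 1136, 1490.0 and 692 CPM and HSP90B1 at 589.6, 741, 1005, 1718, 2129.8 and 1517 CPM, and MANF and SDF2L1 were highest in C5 at 53.3 and 39.7 CPM. Of 72 measured ribosomal protein genes 59 differed, 45 of these with their highest level in C5. RPLP1 was at 732, 879, 1077, 3959, 4239 and 3448 CPM, RPS3A and RPL15 reached 3764 and 641 CPM in C5, and RPL23 differed by a ratio of 1.33. These genes have many near-identical copies, so that single counts are uncertain. The percentiles were 98.8 and 100. Within C4, C5 and C6 alone they were 50.1 and 76.0, and the folding genes were at 90.4 with the median over members.

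All 15 measured secretory granule genes differed, in opposite directions. The granins SCG2 and CHGA were at 48.5, 53.8, 60.9, 1684, 4408 and 453 CPM and 5.15, 11, 12.9, 160.2, 250.0 and 45.9 CPM, while the synaptic vesicle gene VAMP2 and the fusion protein gene SNAP25 were at 1340.4, 1537, 1119, 162, 116 and 206 CPM and 913, 797, 989, 211, 269.9 and 80.2 CPM. SNAP25 is also 1 of the 8 general neuron genes. The list was at percentile 90.7. It was wide under TMM scaling (98.8), DESeq2 scaling (99.7), in TPM (99.3) and within C4, C5 and C6 alone (99.2), and at 67.7 with the median over members. Of the circadian clock genes 10 of 13 differed, with CRY2 at 729, 766, 585, 51.7, 33.5 and 96.9 CPM, HLF at 244, 305, 244, 51.7, 33.5 and 87.3 CPM and NR1D2 between 1.01 and 17.6 CPM. The list was at percentile 96.6, at 46.9 in TPM and at 53.95 within C4, C5 and C6 alone. Cell cycle genes were low, with 4 of 5 measured members past the test and percentile 11.1. PCNA ranged from 15.4 to 59.1 CPM, MCM6 from 18.4 to 62.1 CPM, MCM5 from 2.14 to 11.8 CPM and TYMS from 1.51 to 8.70 CPM. In total, 15 of the 26 lists with at least 3 measured members were called wide. The count of members past the test was the same adjusted over the list alone as over all genes tested, in every list with a measured member.

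**Figure D2:**
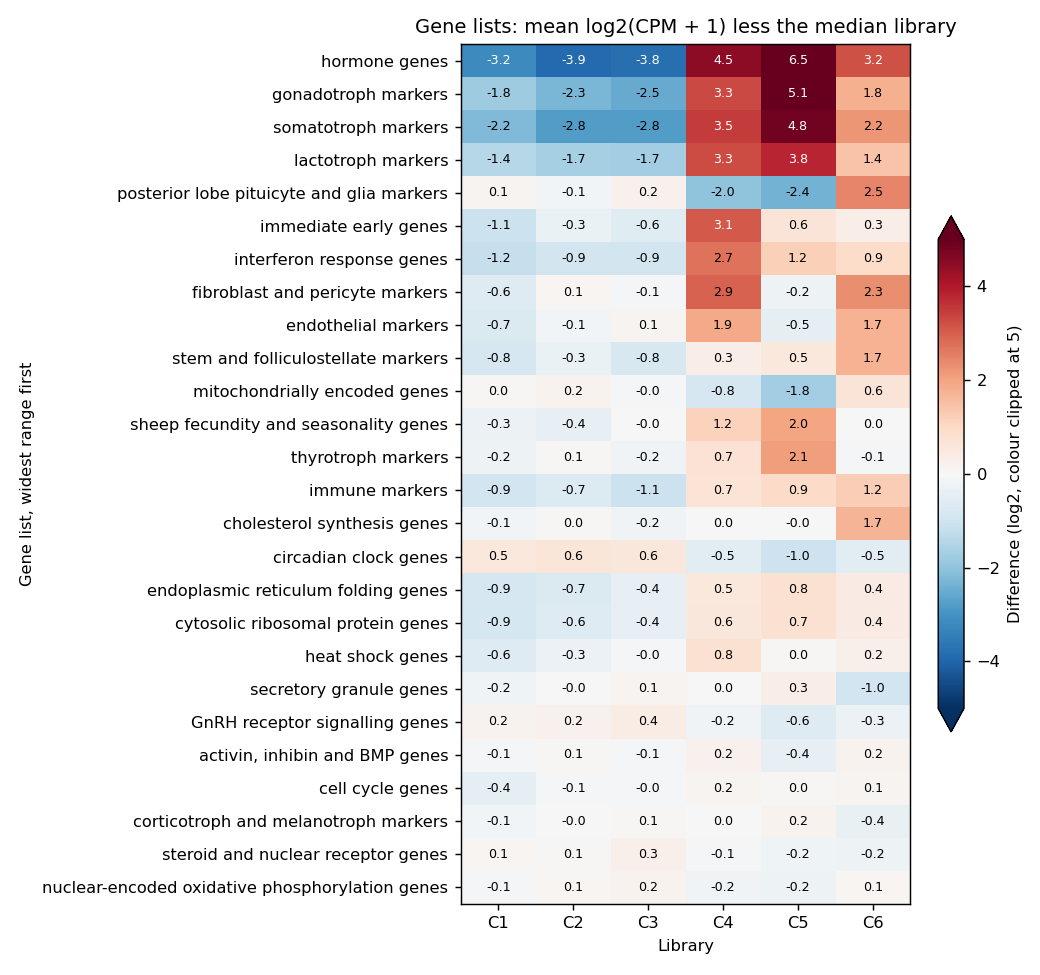
Mean log2(CPM + 1) of each of the 26 gene lists per library, less the median of the 6 libraries (colour scale clipped at 5 on either side), with lists ordered by their range. The hormone genes have a range of 10.34 with the highest mean in C5, the immediate early and interferon response genes are highest in C4, and the posterior lobe and glia markers are highest in C6.

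Of the 15 genes with the highest median CPM, 6 were features without a gene name, led by novel3863 at 37682, 30489.8, 27669.6, 22702, 16107 and 19989 CPM, followed by novel1, novel702, novel1726, novel4610 and novel699, whose ratios of highest to lowest library were between 2.09 and 3.24. ND2, COX3, ND4, ATP8 and ATP6, from the mitochondrial genome, were 5 more, and ATP6 ranged from 598 to 5912 CPM. The others were PRL, S100B, the translation factor gene EEF1A1, at 1006, 1206, 1483, 6339, 6014 and 7716 CPM, and the coatomer gene COPG2, at 5006, 5855, 5578, 3044, 2120.2 and 819.5 CPM. Among the 20 genes with a symbol, a mean of at least 10 CPM and the largest ratios, 5 were hormone genes (GH, PRL, LHB, FSHB and CGA), and 9 had their highest level in C6. ERMN, an oligodendrocyte gene, was at 553, 369, 341, 1.31, 0.413 and 1486 CPM. TTR, the thyroid hormone carrier transthyretin, was at 7312 CPM in C6 and 4521 CPM in C3 but between 4.55 and 111 CPM in the other 4. AGT, CA3, SCRG1, CYTL1 and PLAC9 reached 644, 2198, 353, 933 and 324 CPM in C6. CBLN1, a synaptic organiser of cerebellar granule neurons, was at 1701, 1445, 1394, 1.31, 0.413 and 14.1 CPM, TUBB4A at 1437, 1287, 1147, 3.06, 0 and 1123 CPM and CCN5 at 398, 289, 271, 6.57, 0.413 and 7.06 CPM. IGSF1 was highest in C5 at 298 CPM, and MUSTN1, a musculoskeletal gene, in C4 at 479 CPM.

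Across all genes, 13248 had at least 60 counts over the libraries. Of these, 10723 (80.9%) differed by an adjusted p under 0.05 in the chi-square test of homogeneity with at least a 2-fold ratio between the highest and lowest library, and 3585 had a ratio of at least 10. Within C4, C5 and C6 alone, 3688 of 9166 genes (40.2%) did so. Genes at least 4 times as high as in every other library numbered 213 in C6, 138 in C4, 25 in C5 and 12 in C3, and 0 in C1 and C2. Genes lower than in every other library by at least 4 times numbered 181 in C5, 58 in C6, 15 in C4, 7 in C1, 6 in C3 and 2 in C2. Levels under 1 CPM were set to 1 CPM in both counts. At least 10 counts were found for 12160, 12544, 12752, 12005, 11309 and 11847 genes in C1 to C6, and for 8245 genes in every library. These tests compare libraries, not breeds, and a difference between libraries has no replicate check.

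Spearman's rho across genes was 0.965 between C1 and C2, 0.952 between C2 and C3 and 0.937 between C1 and C3. It was 0.876 between C4 and C5, 0.812 between C4 and C6 and 0.763 between C5 and C6. The other 9 pairs lay between 0.522 and 0.603, and the median of 15 pairs was 0.571. Genes are not independent replicates, so no p is given. As a check for the same library under 2 names, counts were compared within each pair, and the lowest chi-square, for C1 and C2, was 6.32 per gene over 12349 genes. Counting error alone would give about 1, so all 6 libraries were kept as separate samples. Because the values fell into separate sets of fewer than 6 libraries, the planned correlations between hormone genes across libraries were not run, and no correlation across libraries is given.

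**Figure D3:**
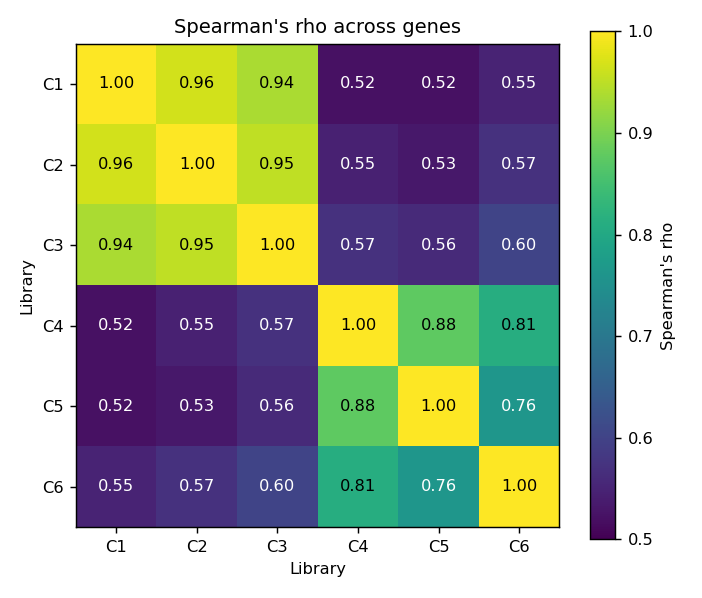
Spearman's rho across 13248 genes for each pair of the libraries C1 to C6 (both axes), from CPM. Pairs among C1, C2 and C3 are at 0.937 or above, pairs among C4, C5 and C6 are between 0.763 and 0.876, and the other 9 pairs are at 0.603 or below.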

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

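The count of genes detected in every library was 14803 with a minimum of 1 count, against 8245 with 10, and stayed within 1.5 times under the other alternatives. The median hormone share was 2.73% without mitochondrial and ribosomal protein genes in the denominator and 1.25% in the authors' TPM, and ran from 0.0139 to 4.71% with each library left out in turn. The leave-one-out range follows from a median that falls between 2 far-apart values, and for TPM the cause was not tested. Genes that differ numbered 6976 at a ratio of at least 4, 4854 with at least 300 counts, and 3688 within C4, C5 and C6 alone, an alternative chosen after seeing the data. The stricter settings keep or test fewer genes, and the last uses fewer libraries and leaves out the contrast with C1, C2 and C3. Between C1, C2 or C3 and C4, C5 or C6, 49.3 to 56.3% of genes were over 2-fold apart. Within pairs of C4, C5 and C6 it was 18.1 to 31.4%. TMM scaling (10578), DESeq2 scaling (10545), thinning (10029), the lower count minimum (13913) and leaving out a library (9272 to 9760) stayed within 1.5 times of 10723. The median Spearman's rho was 0.344 among genes with at least 600 counts, for which the cause was not tested. Wide lists numbered 12 to 19 under all alternatives, against 15. All 15 remained wide under both scalings and 14 in TPM. Of 26 lists, the highest library was the same in 25 under TMM, 23 under DESeq2 and 20 in TPM, and the immune markers were highest in C5 rather than C6 under DESeq2 and TPM. The scalings shifted C5 by 0.21 (TMM) and 0.31 (DESeq2) on the log2 scale, and C3 by -0.10 and -0.16. Of 114 named gene ratios, 88 under TMM and 82 under DESeq2 stayed within their counting interval, and 40 of 100 in TPM. The 2 planned scaling alternatives and the leave-out of 2 libraries for the hormone gene correlations were not run, because the correlations were not. No paired analysis was possible because the labels give no groups to pair. Depth limits statements on genes with few counts, since 0 counts allows up to 1.51 CPM in C6.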

Other observations

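All tests of explanations in this part were chosen after the values were seen, as were the genes and gene lists first named here. The tests of shallow libraries and of cerebellar tissue replaced first versions, with the same outcome, that had compared sets of libraries. TRH, PENK and NEUROD6 were added to the forebrain and hypothalamic lists after 0 of the first 19 genes exceeded 10 CPM in each of C1, C2 and C3, and were chosen because they did. TAGLN was at 24.9, 35.5, 97.2, 3465, 15.7 and 143 CPM in C1 to C6, ACTA2 at 33.4, 37.3, 97.6, 2506, 12 and 74.7 CPM, ACTG2 at 4.29, 1.46, 14.0, 438, 0 and 10.6 CPM and MYH11 at 1.72, 0.732, 3.03, 72.2, 0.827 and 1.51 CPM. In C4, FOS was at 1864 CPM, against 36.9 to 105 CPM elsewhere, and EGR1 at 395 CPM, against 1.72 to 145 CPM. PTGDS, a prostaglandin synthase, was at 2077, 2300.1, 2661, 466, 27.3 and 7376 CPM, and APOD, a lipid carrier, at 205, 120.0, 183, 718, 125 and 5201 CPM.

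The median level of 8 general neuron genes was 1361, 1407, 1369, 51.9, 56.4 and 70.1 CPM. ENO2 was at 2567, 2690.2, 2326, 33.7, 19.4 and 60.1 CPM, RBFOX3 at 843, 509, 465, 13.1, 6.61 and 4.54 CPM, NRXN3 at 3123, 2147, 1878, 23.2, 32.7 and 34.3 CPM and STMN2 at 1808, 2011, 1749, 56, 77.7 and 86.3 CPM. The median level of 6 astrocyte genes was 120.3, 163, 184, 9.19, 6.41 and 172 CPM. Among them, ALDOC was at 2498, 2522, 3182, 46.0, 50.4 and 772 CPM and SLC1A2 at 107, 128, 160.4, 11.8, 3.72 and 201 CPM. The 4 pineal genes summed to at most 7.29 CPM in any library. The mitochondrial share was 3.70, 4.38, 3.80, 2.05, 1.09 and 5.99% of counts and 7.82, 9.45, 9.91, 16.0, 10.2 and 36.1% of the authors' TPM. None of the cerebellar, peripheral myelin or oligodendrocyte genes used here is in a list fixed beforehand, but CBLN1 and ERMN were among the 20 genes with the largest ratios. ATP8 alone took 316708 TPM in C6 against 9327 CPM.

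The hormone share fell into separate sets, at 0.0139, 0.00472, 0.00503, 14.2, 30.0 and 4.71% in C1 to C6. Shallow or failed libraries are argued against, since the lowest total of C1, C2 and C3 was 85.3% of the highest total, and lower hormone expression within pituitary tissue is argued against by 4 pituitary lineage factors (POU1F1, PITX1, TBX19 and LHX3), with 0 summed counts in C1, C2 and C3 and 131, 280 and 30 in C4, C5 and C6. Forebrain or hypothalamic tissue stays open, as 3 of 22 genes exceeded 10 CPM in each of C1, C2 and C3, with TRH at 93.5, 146, 120.0, 0, 0 and 0 CPM, PENK at 88.3, 90.7, 114, 2.19, 0.827 and 1.51 CPM and NEUROD6 at 87.0, 102, 73.8, 0, 0 and 0 CPM, while the other 19, AVP and OXT among them, did not. Cerebellar tissue in C1, C2 and C3 may be a candidate explanation, as 13 of 14 granule neuron and Purkinje cell genes exceeded 10 CPM in each, against 1, 1 and 3 in C4, C5 and C6, with FAT2 at 512, 532, 508, 6.57, 4.55 and 14.1 CPM, GABRA6 at 241, 205, 207, 0.438, 2.07 and 0.505 CPM and PCP2 at 199, 182, 162, 0, 0 and 1.01 CPM. The labels call every library pituitary and give no breed, so whether breed follows these sets was not tested and stays open.

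The low hormone counts in C1, C2 and C3 were weighed as reads carried over from the other libraries. The ratio of GH to PRL counts was 0.0730 (95% interval 0.0418 to 0.119), 0.0988 (0.0412 to 0.204) and 0.149 (0.0711 to 0.282) in C1, C2 and C3. In all 3 the interval met the range of 0.0920 to 0.139 in C4, C5 and C6. With 17, 8 and 11 GH counts the intervals are wide, so the test is weak. The C1 interval met the ratio in C6 but lay below 0.135 in C4 and 0.139 in C5, which held the most PRL counts. Carry-over of reads from the other libraries, GH included, may be a source but stays open. The ratio of CGA to PRL was 0.296, 0.457 and 0.608, and 0 of the 3 intervals met the range of 0.0305 to 0.0582 in C4, C5 and C6, which argues against carry-over of reads from the other libraries as the whole source of CGA. No biological explanation was tested.

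Glial and myelin transcripts were high in C6, where PMP22 was at 1945 CPM and S100B at 9343 CPM. Cerebellar tissue with granule neuron genes at the level of C1, C2 and C3, mixed into C6, is argued against as the source. In C6, 9 granule neuron genes had a median of 1.01% of their lowest level in C1, C2 and C3. S100B in C6 was above its level in those libraries. These 9 genes mark neurons, so the test does not cover white matter of the cerebellum, which stays open. They summed to 57, 24 and 215 counts in C4, C5 and C6, so a small admixture was not excluded. All 4 measured peripheral myelin and Schwann cell genes and all 6 measured oligodendrocyte genes were highest in C6 by at least 2 times, with PRX at 97.4 CPM, GPR37 at 786 CPM and ERMN at 1486 CPM, although ERMN was also at 553 CPM in C1. MOG, of the oligodendrocyte list, was at 238 CPM in C6, so genes of both lists were present together. These values are part of the pattern itself, so they do not decide whether peripheral nerve, central white matter or both were the source. All of these stay open. No other explanation of this pattern was tested.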
